A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

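The series measured transcript levels in Saccharomyces cerevisiae (budding yeast) on 6 Affymetrix arrays of 1 colour. Per the labels' protocols, cultures grew in YPD, a rich glucose medium, at 30 °C with shaking at 250 rpm to an optical density of 1.0. Azinomycin B dissolved in a little ethanol was then added at 100 or 10 µg/ml, or not added, and growth went on for 6 h. The sample annotations give an ED50 (median effective dose) of 10 µg/ml, which is the lower dose. Total RNA was taken with SDS and phenol, and 6 µg was turned into biotin-labelled cRNA, per the labels' protocols. The labels do not mention ethanol in the control cultures. The samples fall into a control group of 3 arrays, a 100 µg/ml group of 2 arrays and a 10 µg/ml group of 1 array. The labels name them A100 and B100 (1 control and 1 treated array each, at 100 µg/ml) and 10 (1 control and 1 treated array, at 10 µg/ml). These names were taken as 2 experiments, the A100 and B100 arrays forming the first and the arrays named 10 the second.

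The deposited values are intensity values, 1 signal per probe set on a linear scale, which the authors made with MAS5, per the submitters' processing notes. The MAS5 version, its scaling target and its background settings are not given in the sources used here. The 2% trimmed mean of the signals lay between 500.32 and 500.40 on every array, a spread of 0.017%, so the values were used as deposited, without further scaling. All 6 value columns matched a sample. The table holds 9335 probe sets. The 60 control probe sets of the manufacturer were left out of the tests, and of the remaining 9275 the 25% with the lowest mean log2 value over the 6 arrays were left out as well, which left 6956. A platform annotation gave 1 gene name to 5670 of these, several names to 282 and none to 1004; over all 9275 the numbers were 6504, 328 and 2443. Gene names come from that annotation and no gene was named from a probe set with several names. Where a gene had several probe sets, the 1 with the highest mean over all 6 arrays stood for it in gene lists, which gave 5173 genes, while probe set counts use all probe sets. Of the tested probe sets, 469 carry the suffix f, 438 the suffix s and 106 the suffix i, marks of the array design for probes that related transcripts can share or that are reduced in number.

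Signals were analysed as log2(signal + 16), so every fold change is on that scale and understates differences of low signals. limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 6 arrays (3 residual degrees of freedom), with moderated two-sided tests and a trend of the variance with signal. P-values were adjusted by the Benjamini-Hochberg method over the 6956 probe sets, with a threshold of 0.05. The 3 contrasts were 100 µg/ml against control, 10 µg/ml against control, and 100 against 10 µg/ml. Since 1 array carries 10 µg/ml, it was assumed to vary like the other groups. Each contrast was also fitted with a control group of its own for each experiment, so that treated arrays were set against controls of the same experiment (2 residual degrees of freedom). The number of arrays limits the precision, and the labels do not say that the arrays come from separate cultures. Differences within a pair are those of the treated array minus the control array of the same label. This pairing rests on the labels alone: A100 minus B100 correlated at r = -0.071 between treated and control arrays.

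Before the data were examined, 37 gene lists were fixed and tested with limma's camera, with a preset correlation between genes of 0.01 and, as an alternative, an estimated correlation, adjusting over the 37 lists. The genes to be named were also fixed then: for 100 µg/ml the 10 largest fold changes each way among probe sets past the threshold with both treated arrays on the same side of all 3 controls and exactly 1 gene name, with the places of missing genes filled from those at an unadjusted p under 0.05; for the other 2 contrasts the 5 largest each way by the same rule; every measured member of the list of DNA damage-induced genes; and, of each other list described, up to 4 members with the largest absolute fold change. No probe set passed, so all of the named genes fill such places. The count of probe sets at which both 100 µg/ml arrays lie at least 2-fold beyond all 3 controls was fixed as a description beside the test.

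Fold changes of the doses were correlated across genes with the 3 controls shared and with the controls of each experiment; the value without any effect came from 100 simulated sets of unchanged arrays. The alternatives were quantile normalization, scaling to a common median, pseudocounts of 1 and 64, no filter, leaving out the lowest 50%, variance without a trend, a threshold of 0.10, leaving out each array in turn, the array label as a block, other sets of controls and, added after the data had been seen, leaving out probe sets numbered 7600 to 8500 and setting each dose against its own experiment in the dose contrast and the gene lists, with a preset or an estimated correlation, leaving out 1 array of the 100 µg/ml experiment in the latter, and an estimated correlation with the block. The fits were tested on simulated data with the control means and fitted spreads of the 6956 probe sets, in 20 draws per contrast with 200 changed probe sets each. Noise was drawn independently for each probe set and array, and no difference between the experiments was simulated. The shares called therefore do not tell what share of changes could be called on the real arrays, where that difference is present. At 100 µg/ml against control, 8.18% of 2-fold, 83.0% of 4-fold and 99.0% of 16-fold changes were called. At 10 µg/ml against control the shares were 2.12%, 47.4% and 97.7%, and for 100 against 10 µg/ml they were 1.60%, 37.2% and 97.1%. Unchanged probe sets were also called, on average 9.15, 7.35 and 6.7 per draw in these 3 contrasts. A list of 30 genes shifted by a log2 value of 1 had a camera p under 0.05 in 20 of 20 draws in each contrast. Without the shift this was so in 2, 0 and 0 draws, over 5173 genes. The list's genes were simulated as independent and tested with the preset correlation only. In the data the estimated correlation reached 0.888, for ribosomal proteins, so these draws do not show that the preset value suits the real lists. With an estimated correlation, camera takes its degrees of freedom from the residuals of the fit. These were 3 in the main fit, 2 with own controls and 1 with the block. With so few, 0 calls over 37 lists was largely set in advance. A call lost there shows neither that correlation between genes explains it nor that it holds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.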

Results

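Transcript levels were measured in budding yeast grown for 6 h with or without azinomycin B, a natural product that cross-links DNA. The series compared the stress response at 100 and 10 µg/ml with control growth. It holds 3 control arrays, 2 arrays at 100 µg/ml and 1 array at 10 µg/ml, with 9335 probe sets each. The labels name the arrays A100, B100 and 10, each name having 1 control and 1 treated array. The median signal was between 111.5 and 142.9 on the 6 arrays, and 15.3% to 18.5% of the signals were under 16. The ratio of the 3' to the 5' probe set of ACT1, which rises as RNA degrades, was 1.69, 2.05 and 1.85 on the control arrays A100, B100 and 10, 2.09 and 1.44 at 100 µg/ml and 1.78 at 10 µg/ml. The bacterial spike-in BioB gave signals of 92.5 to 196.5, and the phage spike-in Cre gave 2693 to 4705. The labels do not say that the arrays come from separate cultures, so p-values measure only the spread between these samples.

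The control of the 10 µg/ml experiment stood apart from the A100 and B100 controls. The A100 and B100 controls correlated at r = 0.980 across the 6956 probe sets tested and differed at least 2-fold at 176 of them. Against both of these, the control of the 10 µg/ml experiment lay at least 2-fold higher at 580 probe sets and at least 2-fold lower at 417. The cytosolic heat shock chaperone SSA4 had signals of 7876 and 8906 in the A100 and B100 controls and 661 in the other control, while the phosphate transporter PHO89 had 271, 395 and 5457. The median of the 65 ribosome biogenesis genes was 1.62 higher (log2) in the control of the 10 µg/ml experiment than in the mean of the other 2, and that of the 24 heat shock genes was 1.15 lower, a log2 difference of -1.15. Each dose is therefore given both against all 3 controls and within its own experiment. The fit with all 3 controls counts this difference as spread within the control group, which can raise its p-values. The treated A100 array differed from its control at least 2-fold at 1167 probe sets, the treated B100 array at 189, and the 10 µg/ml array at 313. The treated A100 array was no closer to the controls of its own experiment (r = 0.906 with A100 and 0.913 with B100) than to the 10 µg/ml array (r = 0.913). Its highest correlation was with the treated B100 array (r = 0.932). The treated B100 array correlated with the A100 control at r = 0.980 and differed from it at least 2-fold at 131 probe sets.

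At 100 µg/ml, HUG1, which encodes a small inhibitor of ribonucleotide reductase and is a target of the DNA damage checkpoint, stood furthest above the controls. Its signal was 43.6 ± 8.04 (SD, n = 3) in the controls, 4369.7 on the A100 array and 477 on the B100 array, a log2 fold change of 4.63 with an SE of 0.843. RNR3, the damage-inducible large subunit of ribonucleotide reductase, had 69.2 ± 30.0 (SD, n = 3) in the controls, 478 and 146.5 when treated (log2 fold change 1.79, SE 0.531). The checkpoint kinase DUN1 had 81.4 ± 24.7 (SD, n = 3), 354 and 196 (1.56, SE 0.373), and the damage-inducible nuclease DIN7 had 103 ± 15.8 (SD, n = 3), 265 and 148 (0.86, SE 0.325). HUG1 was 6.22 and 3.24 higher (log2) than the control of the same label in the A100 and B100 pairs, DUN1 1.85 and 1.59, RNR3 2.90 and 0.44, and DIN7 1.04 and 0.64. With the treated A100 array left out, the fold changes of HUG1, RNR3 and DIN7 were 3.06, 0.99 and 0.48. None of these passed the test (adjusted p = 0.957 for each).

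**Figure D1:**
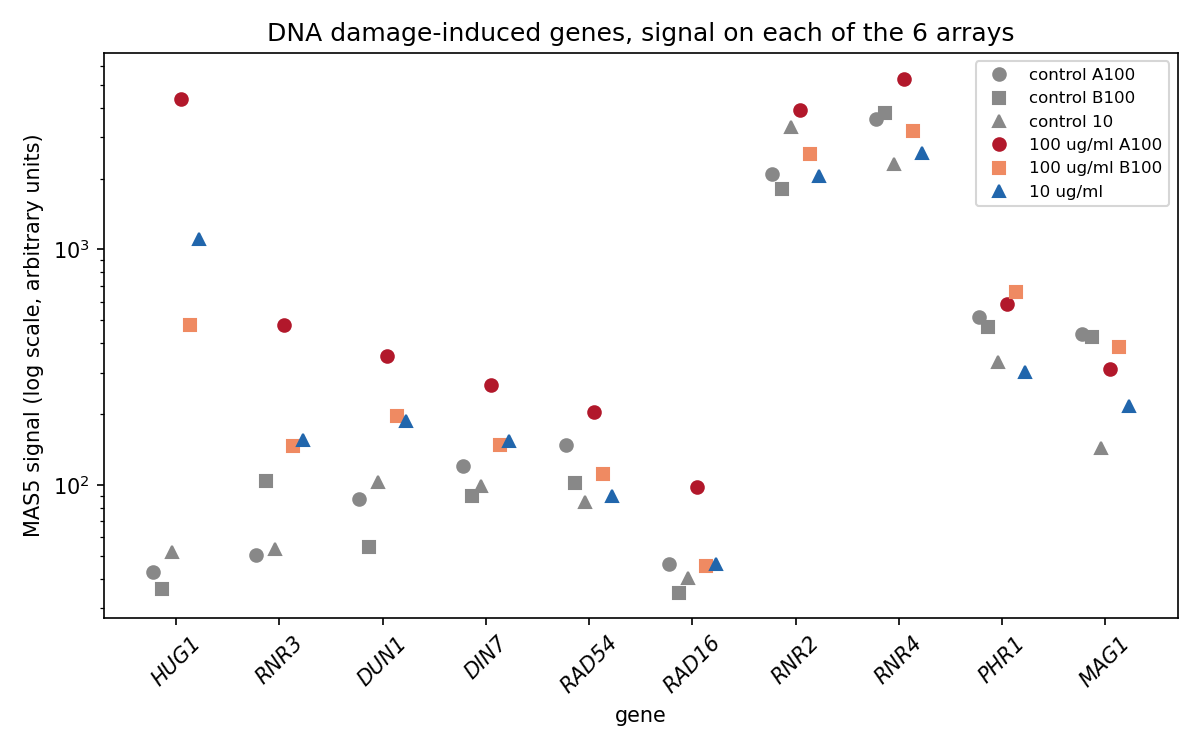
MAS5 signal (log axis, arbitrary units) of 10 of the 15 tested DNA damage-induced genes, with 1 point for each of the 6 arrays. Controls are grey, 100 µg/ml is red and orange, and 10 µg/ml is blue. The 10 genes drawn all had a positive log2 fold change at 100 µg/ml. RFX1 and the 4 members with a negative value (FMP52, DDI1, UBI4 and TSA1) are not drawn. HUG1 lies at 36.1 to 52.1 in the controls and at 477 to 4369.7 on the 3 treated arrays, while RNR2, RNR4, PHR1 and MAG1 overlap between treated and control arrays.

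Of the 15 tested members of the list of DNA damage-induced genes, 11 had a positive and 4 a negative log2 fold change at 100 µg/ml. On both treated arrays 6 members lay above all 3 controls and 1 lay below, where chance gives 10% each way. Besides HUG1, RNR3, DUN1 and DIN7, the positive members were the transcriptional repressor RFX1 (0.62), the nucleotide excision repair gene RAD16 (0.57), the photolyase PHR1 (0.51), the ribonucleotide reductase genes RNR2 (0.44) and RNR4 (0.38), the recombination gene RAD54 (0.42) and the DNA glycosylase MAG1 (0.19). The negative members were FMP52 (-0.42), DDI1 (-0.41), the polyubiquitin gene UBI4 (-0.08) and the peroxiredoxin TSA1 (-0.04). Against the A100 and B100 controls alone, several of these values moved by over 1.5 times: RFX1 was at 0.10, PHR1 at 0.33, RNR2 at 0.70, RNR4 at 0.16, RAD54 at 0.27, MAG1 at -0.31, DDI1 at -0.78, UBI4 at -0.35 and TSA1 at -0.40. With the treated A100 array left out, RAD16 was at 0.13, RNR2 at 0.13, RNR4 at 0.02, RAD54 at 0.03, MAG1 at 0.34, FMP52 at -0.09, DDI1 at -0.10 and UBI4 at -0.03. PLM2, a transcription factor gene of the same list that was under the filter, had signals of 11 ± 4.16 (SD, n = 3) in the controls, 117 and 48.5 at 100 µg/ml and 39.4 at 10 µg/ml. No member passed over all probe sets tested, and 2 passed when adjusted over the list alone. The list's median log2 fold change was 0.44 (camera adjusted p = 0.00393 with the preset correlation, adjusted p = 0.787 with an estimated correlation), with medians of 0.42 and 0.11 in the A100 and B100 pairs. It was 0.13 with the treated A100 array left out and 0.75 with the treated B100 array left out. Within its own experiment the median was 0.27 and the call was lost (adjusted p = 0.310).

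Genes of ribosomal proteins and DNA replication were higher on average at 100 µg/ml, mostly on the A100 array. The 65 ribosome biogenesis genes had a median log2 fold change of -0.03 with 37 negative members (camera adjusted p = 0.369). Their medians were 1.10 in the A100 pair, -0.08 in the B100 pair and 0.47 against the controls of their own experiment (adjusted p = 8.42e-05, adjusted p = 0.762 with an estimated correlation). Of 80 ribosomal protein genes, 76 had a positive log2 fold change, with a median of 0.68 (camera adjusted p = 1.83e-06, adjusted p = 0.787 with an estimated correlation). The median was 2.0 in the A100 pair and 0.34 in the B100 pair. The call was lost with the treated A100 array left out (median -0.000259, adjusted p = 0.193) or the A100 control left out (0.36, adjusted p = 0.0831). RPL9A (1.45, SE 0.653, with 2.49 and 0.10 in the pairs) and RPS9B (1.24, SE 1.10, with 3.64 and 0.86 in the pairs and 2.25 against the A100 and B100 controls alone) had the largest values and did not pass. Of 28 DNA replication genes 24 were positive, with a median of 0.46 (camera adjusted p = 0.00130, adjusted p = 0.787 with an estimated correlation) and medians of 0.92 and 0.22 in the A100 and B100 pairs. They include the sliding clamp POL30 (2.38, SE 0.976, with 4.49 and 2.19 in the pairs) and the clamp loader subunit RFC5 (1.11, SE 0.368, with 1.73 and 0.98), neither of which passed. The value of the helicase subunit MCM4 (-1.62, SE 0.738) rests on the treated A100 array, where its signal was 0.2: its pair differences were -2.56 and -0.36, and its probe set lies in a range of numbers with clustered low values on that array. Of 10 genes of ribonucleotide reductase and its regulators 8 were positive, with a median of 0.56 (camera adjusted p = 0.0123, adjusted p = 0.787 with an estimated correlation), medians of 0.73 and 0.30 in the pairs, and 3 members past the threshold when adjusted over the list alone. RNR1, the main large subunit, was at 0.88 (SE 0.808), and at 1.47 against the A100 and B100 controls alone. Of this list HUG1, RNR3, DUN1, RNR2, RNR4 and RFX1 are also in that of DNA damage-induced genes. The calls of these lists are therefore not independent. All 10 of the G2/M cell cycle genes were positive, with a median of 0.40 (camera adjusted p = 0.0171, adjusted p = 0.787 with an estimated correlation) and medians of 0.66 and 0.05 in the pairs. Among them were the B-type cyclin CLB1 (0.84, SE 0.335, with 1.23 and 0.22 in the pairs) and ALK1 (0.67, SE 0.382). With the treated A100 array left out the replication list (median 0.07, adjusted p = 0.698) and the G2/M list (0.08, adjusted p = 0.885) were not called. The ribonucleotide reductase median was then 0.23. Within their own experiment the ribonucleotide reductase list (median 0.43, adjusted p = 0.0591) and the G2/M list (0.32, adjusted p = 0.220) were not called. With the label as a block, at the same medians, the first was called (adjusted p = 0.0162, adjusted p = 0.863 with an estimated correlation) and the second was not (adjusted p = 0.163).

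Genes of respiration and of growth on carbon sources other than glucose were lower on average, again mostly on the A100 array. Of 23 genes of gluconeogenesis, the glyoxylate cycle and use of non-fermentable carbon 22 had a negative log2 fold change, with a median of -0.75 (camera adjusted p = 2.94e-10, adjusted p = 0.787 with an estimated correlation). The medians were -1.52 in the A100 pair and -0.42 in the B100 pair, and 1 member passed when adjusted over the list alone. Malate synthase MLS1 (-2.85, SE 1.04), the succinate-fumarate carrier SFC1 (-2.36, SE 0.816), alcohol dehydrogenase ADH2 (-1.78, SE 0.822) and the carnitine acetyltransferase YAT1 (-1.71, SE 0.343) led this list. ADH2 was at -0.96 against the A100 and B100 controls alone, since its signal was 6727 in the control of the 10 µg/ml experiment and 879 and 1642 in these 2. All 16 of the tricarboxylic acid cycle genes were negative, with a median of -0.45 (camera adjusted p = 1.12e-07, adjusted p = 0.787 with an estimated correlation), medians of -0.70 and -0.20 in the pairs, FUM1 at -0.79 (-1.16 and -0.28 in the pairs, also in the range with clustered low values) and ACO1 at -0.76 (-1.57 and -0.10 in the pairs). Of 34 nuclear genes of the respiratory chain and ATP synthase 31 were negative, with a median of -0.30 (camera adjusted p = 1.34e-06, adjusted p = 0.787 with an estimated correlation), and medians of -0.50 and -0.17 in the pairs. Its members with the largest values were less even: ATP20 (-0.96) was at -2.28 in the A100 pair and 0.09 in the B100 pair, next to MCM4 in the range with clustered low values, and CYC7 (0.73) was at -0.04 against the A100 and B100 controls alone. The 14 M/G1 cell cycle genes had a median of -0.32 (camera adjusted p = 0.0236, adjusted p = 0.787 with an estimated correlation), with -0.47 in the A100 pair and 0.13 in the B100 pair. ASH1, a repressor made in daughter cells, and PRY3 were both at -0.87. The 22 genes of vacuolar proteolysis and autophagy had a median of -0.18 (camera adjusted p = 0.0479, adjusted p = 0.787 with an estimated correlation), medians of -0.56 and -0.10 in the pairs and 0.12 with the A100 treated array left out, and were led by the carboxypeptidase CPS1 (-1.02). With the treated A100 array left out the medians were -0.17 for gluconeogenesis and -0.13 for the tricarboxylic acid cycle. The respiratory chain (-0.05, adjusted p = 0.269), M/G1 (-0.05, adjusted p = 0.447) and vacuolar (adjusted p = 0.988) lists were not called. M/G1 was also not called with the A100 control left out (-0.21, adjusted p = 0.129), nor was the vacuolar list with the A100 control (-0.17, adjusted p = 0.348) or the B100 control (-0.16, adjusted p = 0.144) left out.

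Of the 37 lists fixed, camera called 10 at 100 µg/ml with the preset correlation, 5 higher and 5 lower, and 0 with an estimated correlation. That last count was largely set in advance by the few residual degrees of freedom. Against the controls of their own experiment 13 were called, 7 of these 10 among them in the same direction, and 0 with an estimated correlation, where the lowest adjusted p was 0.762. The 6 lists gained there were ribosome biogenesis (median 0.47, adjusted p = 8.42e-05), G1/S cell cycle genes (0.87, adjusted p = 0.00846), silent and subtelomeric families (0.43, adjusted p = 0.0294), the induced environmental stress response (-0.29, adjusted p = 2.44e-06), the proteasome (-0.22, adjusted p = 0.000418) and heat shock proteins (-0.26, adjusted p = 0.00115), each with adjusted p = 0.762 with an estimated correlation. With the label as a block, at the same median, the silent and subtelomeric list was not called (camera adjusted p = 0.0591). Against all 3 controls the medians of the 6 lists were -0.03, 0.24, 0.29, 0.05, 0.01 and 0.19, of the other sign for ribosome biogenesis and the last 3. Without the A100 treated array 6 were called. The lists of DNA repair genes were not among those called. The list of recombination and crosslink repair had a median of 0.22 (camera adjusted p = 0.515), with the helicase SRS2 at 0.78 and the crosslink repair nuclease PSO2 at 0.53 (0.24 against the A100 and B100 controls alone), that of nucleotide excision repair -0.04 (adjusted p = 0.752) and that of base excision repair 0.19 (adjusted p = 0.325). The DNA damage checkpoint list had a median of 0.25 (adjusted p = 0.0937).

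**Figure D2:**
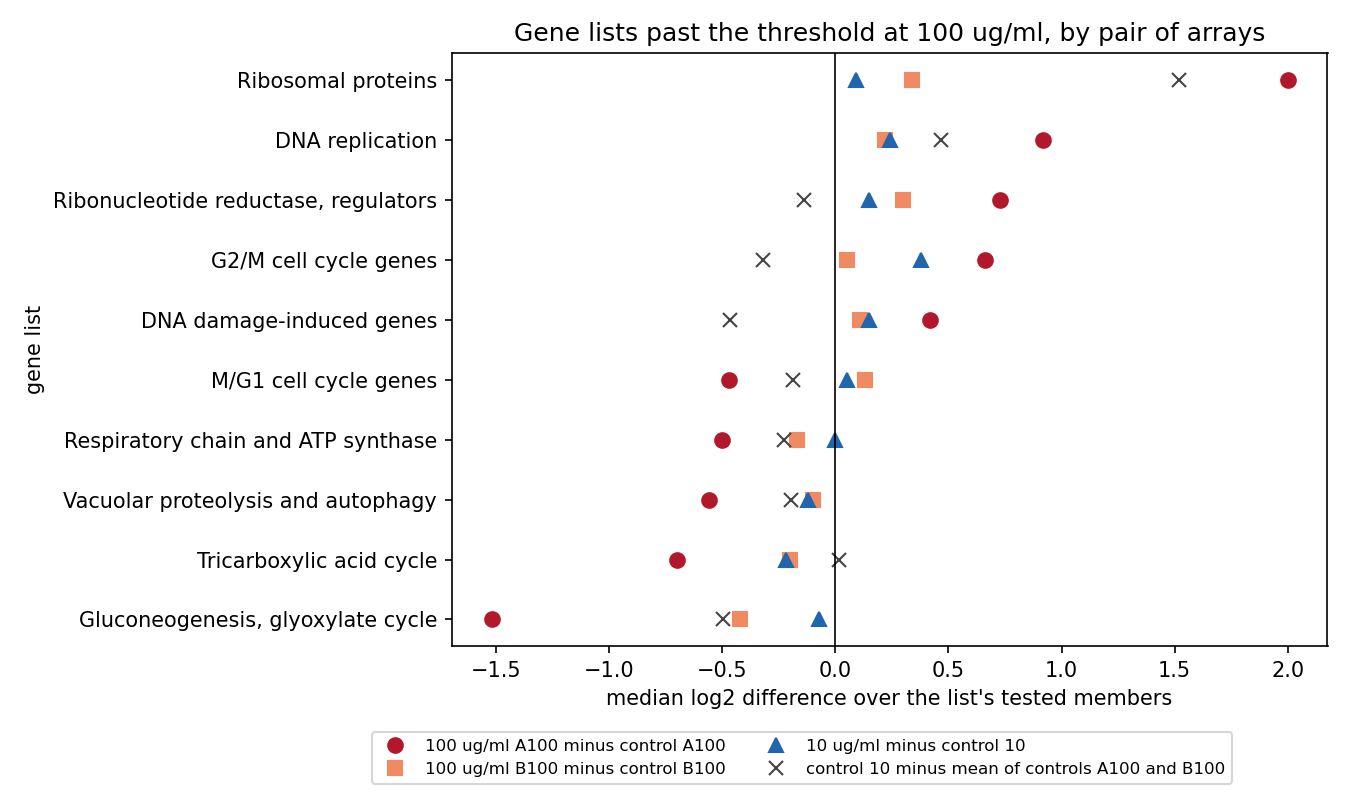
Median log2 difference over the tested members (x axis) of the 10 gene lists called at 100 µg/ml (y axis), for each treated array minus the control of the same label and, as crosses, for the control of the 10 µg/ml experiment minus the mean of the other 2 controls. The ribosomal protein median is 2.0 in the A100 pair, 0.34 in the B100 pair and 0.09 in the 10 µg/ml pair, and 1.52 between the controls.

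Among single genes at 100 µg/ml with both arrays above all 3 controls, the mating pheromone genes MFA1 (log2 fold change 2.09, SE 0.775) and MF(ALPHA)2 (2.09, SE 0.747), the translation factor gene ANB1 (1.91, SE 0.689) and the NADPH oxidoreductase OYE3 (1.91, SE 0.783) followed HUG1. CRG1, a methyltransferase (1.82, SE 0.665), SPH1, which acts in polarised growth (1.80, SE 0.522), RNR3 (1.79), RSR1, a GTPase of bud site selection (1.64, SE 0.643), and DUN1 (1.56) came next. Against the A100 and B100 controls alone OYE3 was at 1.16 and CRG1 at 1.18, under RSR1 (1.75), SPH1 (1.72) and DUN1 (1.72). MFA1 was 3.98 higher in the A100 pair and 0.53 higher in the B100 pair on this probe set, whose suffix marks probes shared by related transcripts, and 0.25 and 0.47 higher on its other tested probe set, so the large A100 value is not borne out by both. RSR1 was 3.15 and 0.36 higher, and 2.07 and 0.61 on its other probe set. ANB1 was 3.13 and 0.40 higher in the A100 and B100 pairs, MF(ALPHA)2 3.15 and 1.14, OYE3 1.73 and 0.58, CRG1 1.57 and 0.80, and SPH1 2.87 and 0.56. With the treated A100 array left out, MFA1 was at 0.71, MF(ALPHA)2 at 0.74, ANB1 at 0.67, OYE3 at 1.26, SPH1 at 0.94 and RSR1 at 0.51, so these values depend on that array. On the lower side, OLI1 (-3.42, SE 0.877) and COX1 (-2.41, SE 0.518), which encode subunits of ATP synthase and cytochrome oxidase in the mitochondrial genome, stood beside MLS1 and SFC1. The glycerol transporter STL1 (-2.12, SE 0.788), the carnitine acetyltransferases YAT2 (-1.93, SE 0.684) and YAT1, the transcription factor PHD1 (-1.61, SE 0.371), GPB1 (-1.57, SE 0.464) and PDH1, of propionate metabolism (-1.53, SE 0.378), completed this group. YAT1 was lower to a like extent in both pairs (-1.52 and -1.58), while the others were less even. STL1 was at -3.10 and -0.52, YAT2 at -2.71 and -1.19, PHD1 at -2.30 and -0.97, GPB1 at -2.28 and -0.74 and PDH1 at -1.56 and -1.11. With the treated A100 array left out, STL1 was at -0.76, YAT2 at -0.74, GPB1 at -0.80, PHD1 at -1.06, MLS1 at -0.91 and SFC1 at -0.89. The probe sets of GPB1 and PDH1 lie in the range of numbers with clustered low values on that array, and GPB1 is itself among the low ones. In the controls OLI1 ranged from 267 to 1969. None of these genes passed the test.

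For 100 µg/ml against control, limma called 0 of 6956 probe sets at an adjusted p under 0.05, with a lowest adjusted p of 0.957 and 232 probe sets at an unadjusted p under 0.05, where chance alone gives 348. With 1 array left out of this fit the latter count was 30 without the treated A100 array, 679 without the treated B100 array and 113 without the B100 control. Against the controls of the same experiment limma also called 0, with 425 at an unadjusted p under 0.05. The fit with all 3 controls counts the difference between the experiments as spread, so its count under 348 does not show an absence of effect. On both treated arrays 12.3% of the probe sets lay above all 3 controls and 7.58% lay below, where chance gives 10% each way. Just 3 probe sets lay at least 2-fold beyond all 3 controls on both treated arrays, HUG1 above and COX1 and YAT1 below. The A100 array alone did so at 169 probe sets above and 169 below, and the B100 array alone at 4 above and 4 below.

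At 10 µg/ml the signal of HUG1 was 1109.8, a log2 fold change of 4.25 (SE 1.07) against all 3 controls and a log2 difference of 4.05 from the control of its own experiment. DUN1 (1.10, SE 0.472) and RNR3 (1.06, SE 0.671) had differences of 0.78 and 1.30 within the pair. The other genes with the largest values above all 3 controls were DBP3 (2.41, SE 0.746), an RNA helicase of ribosome biogenesis, NIP7 (2.19, SE 0.893) and FCF2 (2.13, SE 0.630), which act in the same process, and the tRNA methyltransferase TRM8 (1.90, SE 0.771). Within the pair these 4 were at 1.63, 0.72, 1.33 and 0.76. NIP7 had signals of 13.5 and 15 in the A100 and B100 controls, under the pseudocount of 16. Below all 3 controls were BTN2 (-3.77, SE 0.929), a chaperone of protein sorting, the heat shock protein SSA4 (-3.74, SE 1.38), YGR111W (-2.26, SE 0.453), the vacuolar ATPase subunit VMA1 (-2.21, SE 0.453) and AIM17 (-2.12, SE 0.376). Within the pair these were at -2.19, -1.32, -1.71, -1.73 and -1.76. The other tested probe set of VMA1 was at -0.81, and at -0.31 within the pair. None of these genes passed the test (adjusted p = 0.761 for each). The DNA damage-induced list had a median log2 fold change of -0.30 and a mean of 0.16 (camera adjusted p = 0.455, on the lower side); within its own experiment the median was 0.15 (adjusted p = 0.690).

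Against all 3 controls, camera called 17 lists at 10 µg/ml, 7 higher and 10 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.703. Against the control of the same experiment it called 2 of them with the preset correlation, and 0 with an estimated one (lowest adjusted p 0.965), those of glycolysis (median -0.15, adjusted p = 0.0109, adjusted p = 0.965 with an estimated correlation) and the tricarboxylic acid cycle (median -0.22, adjusted p = 0.0364, adjusted p = 0.965 with an estimated correlation). The 65 ribosome biogenesis genes were all positive against the 3 controls, with a median of 1.23 (camera adjusted p = 5.83e-12, adjusted p = 0.703 with an estimated correlation), and had a median of 0.23 in the pair (adjusted p = 0.690). All 24 of the heat shock genes were negative, with a median of -0.69 (camera adjusted p = 3.67e-09, adjusted p = 0.703 with an estimated correlation), and -0.06 in the pair (adjusted p = 0.0856), or -1.13 with the control of the 10 µg/ml experiment left out. With the label as a block, at the pair median, the heat shock list was called with the preset correlation but not with an estimated one. In the controls the ribosome biogenesis and heat shock lists lay 1.62 higher and 1.15 lower (log2 -1.15) in the 10 µg/ml experiment than in the other. The hexose transporters HXT7 (-1.40, SE 0.259) and HXT6 (-1.14, SE 0.262) were the 2 members of any list past the threshold when adjusted over the list alone, with pair differences of -1.38 and -1.19.

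limma called 0 of 6956 probe sets for 10 µg/ml against control (lowest adjusted p 0.761), with 291 at an unadjusted p under 0.05. This count was 101 without the A100 control, 135 without the B100 control and 1603 without the control of the 10 µg/ml experiment. The array lay above all 3 controls at 33.1% of the probe sets and below them at 21.7%, where chance gives 25% each way. With the control of the same experiment 0 were called and 254 had an unadjusted p under 0.05. Without that control 4 were called, in a comparison that then rests on the controls of the other experiment. This dose has 1 array and no replicate check.

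Between the doses, the largest differences were those that also separate the controls of the 2 experiments. SSA4 (log2 fold change 4.68, SE 1.46), BTN2 (4.50, SE 0.986), the zinc finger protein ZPR1 (4.24, SE 1.38), the chaperone SSA2 (3.97, SE 1.36) and the kinase RCK1 (3.64, SE 1.38) were higher at 100 than at 10 µg/ml. With each dose set against the controls of its own experiment their differences were 1.05, 2.12, 0.83, 0.65 and 0.33. The value of RCK1 is set by the pseudocount, since its signals were 1.5 and 0.6 in the 10 µg/ml experiment: it was 6.91 with a pseudocount of 1 and 1.98 with 64. PHO89 (-4.57, SE 1.61), the decarboxylase ARO10 (-4.07, SE 1.69), YOR302W (-4.06, SE 1.27), NIP7 (-3.06, SE 0.947) and ADH2 (-2.98, SE 1.10) were lower, and in that fit were at -0.58, 0.15, -1.39, -0.85 and -0.51. None of these passed (adjusted p = 0.764 for each). HUG1 differed by 0.39 (SE 1.13), and by 0.69 against the controls of its own experiment. NIP7 had signals of 6.6 to 17.9 in the 100 µg/ml experiment, around the pseudocount of 16, so its value depends on the pseudocount. The probe sets of NIP7 and YOR302W lie in the range of numbers with clustered low values on the treated A100 array. YOR302W was at -1.77 in the A100 pair and -0.63 in the B100 pair.

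limma called 0 of 6956 probe sets between the doses, with 395 at an unadjusted p under 0.05, and 0 with each dose against its own controls, with 234. The count of 395 was 226 without the treated A100 array, 251 without the B100 control and 1070 without the control of the 10 µg/ml experiment, where 5 were called. With the preset correlation camera called 11 lists, and 0 with an estimated correlation, where the lowest adjusted p was 0.865. In the fit with own controls, chosen after seeing the data, it called 2. Ribosomal proteins were lower at 100 than at 10 µg/ml over all arrays (median -0.43, adjusted p = 0.0285, adjusted p = 0.865 with an estimated correlation) and higher with own controls (median 0.98, adjusted p = 3.09e-13, adjusted p = 0.987 with an estimated correlation). Over all arrays that median was -1.14 with the treated A100 array left out and 0.22 (adjusted p = 0.0799) with the treated B100 array left out. With own controls and the same arrays left out it was 0.33 and 1.77. All 15 DNA damage-induced genes were positive between the doses (median 0.62, adjusted p = 0.00353, adjusted p = 0.865 with an estimated correlation), while with own controls the median was 0.20 (adjusted p = 0.862). Over all arrays the call was lost with the treated A100 array left out (median 0.31, adjusted p = 0.137).

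Across the probe sets the fold changes at 100 and 10 µg/ml correlated at r = 0.183 (Spearman 0.194) with the 3 controls shared (covariance 0.0523), where 100 simulated sets without an effect gave a mean of 0.316 (covariance 0.0638). The simulation holds no difference between the experiments, which moves these fold changes in opposite directions, so the observed value lying under the simulated one does not show less agreement than chance. With the controls of each experiment, which share no array, r was 0.162 (Spearman 0.168, covariance 0.0392) and 56.9% of the probe sets had the same sign. The A100 and B100 pairs correlated at 0.240, the A100 pair and the 10 µg/ml pair at 0.217, and the B100 pair and the 10 µg/ml pair at -0.0397. Genes are not independent replicates, so no p-value is given.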

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

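All tests of explanations given here were chosen after the result was seen. The response of 2 gene lists differed between the doses when each dose was set against the controls of its own experiment. The median difference, 100 minus 10 µg/ml, was 0.98 for 80 ribosomal protein genes (camera adjusted p = 3.09e-13, adjusted p = 0.987 with an estimated correlation) and -0.91 for 23 genes of gluconeogenesis, the glyoxylate cycle and non-fermentable carbon use (adjusted p = 0.00552, adjusted p = 0.987 with an estimated correlation). Within their own experiments the ribosomal protein medians were 1.17 at 100 µg/ml and 0.09 at 10 µg/ml, and those of the other list -0.92 and -0.07. Both differences rest largely on the treated A100 array: with it left out they were 0.33 (adjusted p = 3.64e-05, adjusted p = 0.990 with an estimated correlation) and -0.28, where the second was not called (adjusted p = 0.633), and with the treated B100 array left out they were 1.77 and -1.55.

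The treated A100 array stood further from the controls than the treated B100 array, and both list shifts were larger in its pair. Control RNA on the B100 array is argued against by HUG1, which lay 2.86 (log2) above the highest control there, a level that 0 of 6956 probe sets reached on the A100 or B100 control. The control of the 10 µg/ml experiment was not counted and does reach it, as for PHO89 (5457, against 271 and 395 in the A100 and B100 controls). As to RNA degradation, the 3' to 5' ratios of ACT1, YER148W and YER022W on the treated A100 array were 2.09, 3.77 and 6.71. The highest control, B100 for each, had 2.05, 5.15 and 8.07, and 0 of 3 ratios exceeded 1.5 times these. Against the A100 control (1.69, 4.01 and 4.40) ACT1 and YER022W were higher and YER148W was lower. Strong degradation beyond the spread of the controls is argued against, while a smaller difference from the A100 control stays open. A difference in growth stage stays open as a hypothesis: across 5173 genes the A100 pair difference correlated at r = 0.409 with the control of the 10 µg/ml experiment minus the B100 control, and the matching value for the B100 pair was 0.0819. No growth measurement was used here, and a dose effect on growth and a culture at another stage cannot be separated by this test. The ED50 given with the samples is 10 µg/ml, the lower dose, and was not used in this test.

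On the treated A100 array 78 tested probe sets (1.12%) lay at least 4-fold under the control of that label, against 1 in the B100 pair and 4 in the 10 µg/ml pair. Of the 78, 23 stood next to another in the numbering of the array, where the highest of 100 shuffles gave 8, and 41 lay between numbers 7600 and 8500; a defect of the array surface gives such runs, provided the numbering follows position on the array, which was not checked. The same probe sets had medians of -2.94 in the A100 pair, -0.0359 in the B100 pair and 0.229 in the 10 µg/ml pair. Loss of the whole chromosome segment under the longest span is argued against by its 269 tested probe sets, 24 of them low, with a median of -0.144; loss of short segments was not tested and stays open, since HST2, CIP1 and MRPS16, at -5.54, -3.52 and -3.63 in the A100 pair, are neighbours in number and also in the genome. Leaving out that numbering range left the A100 pair medians of ribosomal proteins and gluconeogenesis at 2.02 and -1.54.

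OLI1 and COX1, both encoded in the mitochondrial genome, were lower in all 3 pairs, at -5.36, -0.99 and -2.48 for OLI1 and -3.67, -1.14 and -1.53 for COX1. The 20 nuclear probe sets nearest in number, up to 40 numbers away, had a lowest median over the 3 pairs of -0.0555. This argues against a local defect of the array surface only if the numbering follows position on the array, which was not checked. A first version of this test, with a narrower neighbourhood, held no probe set and was replaced. Variation in RNA preparation between cultures stays open, since the gap between the lowest control and the highest treated array was 0.352 for OLI1 and 0.927 for COX1, against control ranges of 2.81 and 1.15. An effect of the compound on mitochondrial transcripts also stays open and was not tested.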

How the results depend on the processing

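Leaving out the probe sets numbered 7600 to 8500 and the own controls in the dose contrast and the gene lists, with a preset or an estimated correlation or 1 array of the 100 µg/ml experiment left out, and an estimated correlation with the block, were chosen after seeing the data; the other alternatives were planned. Where a result moved, the cause was not tested, apart from settings whose construction gives fewer arrays. Of 779 values of named genes under alternatives 763 kept direction and side of the threshold, 7 passed and 9 turned. Of 506 list values 375 kept both, 117 lost the call and 14 turned. No named gene passed in the main fit and most were chosen for large fold changes. For genes, keeping both was therefore largely set in advance. At 100 µg/ml MLS1 ranged from -4.80 to -0.91 and RAD54 from 0.03 to 0.81 without turning or passing. Low signals limit the array: 15.3% to 18.5% were under 16.

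Leaving out 1 array at a time, with a lone array assumed to vary like the others, the probe sets called ranged from 0 to 0 at 100 µg/ml, 0 to 4 at 10 µg/ml and 0 to 5 between doses. Lists called ranged from 6 to 14, 13 to 17 and 11 to 14. The 2-fold set ranged from 4 to 169 above and 4 to 169 below. BTN2 and SSA4 at 10 µg/ml (adjusted p = 0.0164, range over alternatives 0.0164 to 1) and SSA4, BTN2 and ZPR1 (0.0170 to 0.966), PHO89 (0.0245 to 0.966) and ARO10 (0.0245 to 0.971) between doses passed without control 10 alone. At 100 µg/ml TSA1 ranged from -0.40 to 0.23, UBI4 from -0.35 to 0.0612 and MAG1 from -0.31 to 0.45. The list medians ranged from -0.000259 to 1.37 for ribosomal proteins and -0.34 to 0.12 for vacuolar proteolysis at 100 µg/ml, and from -1.14 to 0.22 for ribosomal proteins between doses.

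Quantile normalization turned TSA1 at 100 µg/ml to 0.14 and the respiratory chain at 10 µg/ml to 0.0452, and 11 lists were called at 10 µg/ml, against 17. With an estimated correlation 0 lists were called at 100 µg/ml, 0 at 10 µg/ml and 0 between doses. This test has only the 3 residual degrees of freedom of the fit, so these counts were largely set in advance. Hexose transporters at 10 µg/ml lost the call although their estimated correlation (-0.0783) lay under the preset 0.01. The 2-fold set held 3 above and 4 below with a pseudocount of 1, 0 below with 64, 4 above with no filter, and 14 above and 9 below with controls A100 and B100 only, where MAG1 was -0.31. With control 10 only, 2 lists were called at 10 µg/ml, the proteasome median was 0.0167 and that of DNA damage-induced genes 0.15. With own controls between doses 2 lists were called, ARO10 was 0.15, and medians were -0.21 for heat shock, -0.27 for the environmental stress response, -0.0485 for oxidative stress, -0.20 for the proteasome, 0.98 for ribosomal proteins and 0.27 for ribosome biogenesis.

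With the label as a replicate block, 0 probe sets were called at either dose, with 473 and 188 at an unadjusted p under 0.05 at 100 and 10 µg/ml, and 13 and 3 lists. With an estimated correlation no list was called at either dose in this fit. The fit has 1 residual degree of freedom, so that outcome was largely set in advance and decides nothing. MAG1 was -0.31, the proteasome median at 10 µg/ml 0.0167 and that of DNA damage-induced genes 0.15, and the 2-fold set by pair held 30 above and 20 below. The arrays of a pair share a label (A100, B100 or 10), which does not say that they were matched. A100 minus B100 correlated at r = -0.071 between treated and control arrays, so the values do not bear out the A100 and B100 pairing.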

Other observations

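The single genes described here were chosen after their values were seen, the list of silent and subtelomeric families before, and of the tests of explanations only that over the 3 pairs was chosen before. The fixed list of hexose transporters had 10 tested members. Among them was the glycerol transporter STL1, far below the control in the A100 pair (-3.10, with -0.52 in the B100 pair). The list was not called at 100 µg/ml (median 0.22, camera adjusted p = 0.753, with a median of -0.07 in the A100 pair), but 3 of its members stood far above the control in the A100 pair. It was called at 10 µg/ml (median -0.29, adjusted p = 0.0213, adjusted p = 0.703 with an estimated correlation). It was not called within that experiment (-0.16, adjusted p = 0.273) or without its control (-0.46, adjusted p = 0.0966). Between the doses it was also called (1.00, adjusted p = 0.0285, adjusted p = 0.865 with an estimated correlation). It was not called with own controls (1.00, adjusted p = 0.319), without the treated A100 array (0.49, adjusted p = 0.114) or without the control of the 10 µg/ml experiment (adjusted p = 0.0806). HXT2 had a signal of 77.0 in the A100 control and 4027 on the treated array, a log2 difference of 5.44, against 0.56 in the B100 pair and 0.59 in the 10 µg/ml pair. HXT4 was at 3.39, 0.29 and 0.11 and HXT3 at 3.38, 0.43 and 0.06. At 10 µg/ml HXT7 and HXT6, high-affinity transporters, were at -1.38 and -1.19 in the pair, while in the A100 pair they were at -0.07 and -0.06. Their probe sets share the suffix for related transcripts.

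The signals of the alpha-cell genes MF(ALPHA)1 (6398 in the A100 control), SAG1 (4273) and STE3 (758) were high on all arrays. The fixed list of mating type and pheromone genes was not called at 100 µg/ml (median 0.25, camera adjusted p = 0.210; own experiment 0.23, adjusted p = 0.220). It was called at 10 µg/ml (median 0.37, adjusted p = 0.0458, adjusted p = 0.703 with an estimated correlation). It was not called within that experiment (0.40, adjusted p = 0.491), without the A100 control (adjusted p = 0.0522) or without the control of the 10 µg/ml experiment (adjusted p = 0.105). Of genes normally expressed in a cells, MFA1 was at 3.98, 0.53 and 1.29 in the A100, B100 and 10 µg/ml pairs on the probe set with the suffix for shared probes and at 0.25, 0.47 and 1.28 on its other tested probe set. MFA2 was at 0.79, 0.38 and 1.12, BAR1 at 1.76, 0.72 and 0.81 and AGA2 at 1.94, 0.29 and 0.43. STE6 was at -0.03, 0.33 and -0.38, and, under the filter, ASG7 at 1.43, 0.29 and -0.11 and the receptor gene STE2 at 0.20, 0.07 and 0.32, with 3 probe sets of HMRA1 between -0.47 and 0.21. Of the alpha-cell genes, MF(ALPHA)1 was at -0.13, -0.22 and -0.32, SAG1 at -0.25, -0.23 and -0.12 and STE3 at 0.04, -0.17 and 0.50. MF(ALPHA)2 (3.15, 1.14 and 0.89) and AFB1 (0.63, 0 and 0.54), also of alpha cells, were not lower. The 9 genes of silent and subtelomeric families were all positive at 100 µg/ml (median 0.29, camera adjusted p = 0.0682), with pair medians of 0.24, 0.31 and 0.39. Against the controls of its own experiment the list was called (median 0.43, adjusted p = 0.0294), though not with an estimated correlation (adjusted p = 0.762 with an estimated correlation). With the label as a block, at the same median, it was not called (adjusted p = 0.0591). PAU7 was at 0.91, or 0.54 against these controls, and COS10 at 0.58. None of these genes passed the test.

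At least 2-fold differences in the same direction in all 3 pairs were found at 3 probe sets, HUG1 and an unnamed one higher and COX1 lower. Of the 4 patterns of signs over the pairs 2 gave as many, and the highest of the others gave 3. The patterns are too few for a share under 0.05.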
